A study of Mus musculus with 17 samples.

How the data were processed

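The samples were whole retinas of male C57BL6/J mice. Per the labels' protocols, diabetes was induced at 8 weeks of age with 1 injection of streptozotocin (160 mg/kg), a toxin of insulin-producing beta cells. The series held 17 arrays: 6 of non-diabetic control mice, 6 of mice left diabetic for 12 weeks, and 5 of mice that were diabetic for 6 weeks and then carried transplanted pancreatic islets and insulin-releasing pellets for 6 more weeks. Groups and replicate numbers were taken from the sample titles, which call the replicates biological, so p-values measured the spread between animals of a group. Benfotiamine-fed mice and mice examined at 6 weeks, which the labels' protocols mention, were not analysed here.

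Per the labels' protocols, eyes were snap-frozen, retinas were dissected from them on ice, total RNA was extracted with Trizol, and biotin-labelled cRNA was prepared by the standard Affymetrix procedure. Per the submitters' processing notes, the authors used RMA, a method that corrects background, equalises the distribution of values between arrays and summarises probes; its version, the array type, the chip definition and the genome build are not given in the sources used here. The deposited values were log2 expression values, 1 per Entrez gene number and array. All 17 arrays held the same distribution, with a minimum of 5.07, a median of 5.73, an upper quartile of 7.20 and a maximum of 14.1. Of the values, 100% were whole multiples of 1/1024 to within a small fraction of that step. A shift of all genes together between groups therefore cannot be seen in these values, and changes were relative to the other genes of an array. Equalised distributions and background correction also compress differences of dim genes. The number of arrays per group limited the precision.

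Of 24973 rows, 24015 had 1 gene symbol, 0 had several and 958 had none. Of the symbols, 4 stood on 2 rows, of which the brighter was used, which left 24011 genes. The kind of gene was taken from a reference table of assembly GRCm38.p6, where 23922 symbols matched; no coordinates are given, because the build behind the array annotation is not stated. No filter on dim genes was used.

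A linear model with a mean per group was fitted to all 3 groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings). Contrasts of each pair of groups and the moderated F over the groups were tested, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05 over all 24011 genes. The model and the comparisons were tested on simulated data with changed genes of known size. Changed genes were drawn from those above the 40th percentile of intensity, so the recovery does not cover dim genes. The simulated noise was independent between genes and arrays, which the real arrays need not be. In each contrast 67, 67 and 66 genes were changed by 0.25, 0.5 and 1 on the log2 scale. For diabetic against control, 41, 64 and 66 of these were recovered. Among unchanged genes, 11, 7 and 8 were called for diabetic against control, transplanted against control and transplanted against diabetic. With a log2 change of 0.25, 61.2% of the changed genes were recovered for diabetic against control, 62.7% for transplanted against control and 67.2% for transplanted against diabetic. With a log2 change of 0.5, 95.5%, 95.5% and 97.0% were recovered, respectively.

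The design, 40 gene lists of retinal cell types, other eye tissues, stress responses and metabolism, and the rule for naming genes were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists of a contrast; camera with an estimated correlation and fry were run beside it. Genes named were the 10 largest rises and the 10 largest falls among called genes, up to 4 members with the smallest p of each list that was shifted or had a called member, 19 genes fixed by name, of which 17 had a named row, and the 10 genes with the smallest F p among those called in several contrasts; the text names a part of them. Of lists, only some are described singly.

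To ask whether the diabetic change was still present after transplantation, log2 changes of the contrasts were correlated across genes. Because the contrasts share arrays, the same value was computed for simulated unchanged groups and with the shared group split 3 against 3 over 20 splits. Alternatives covered the filter on dim genes, the row per gene, normalization, the variance model, array weights, the samples in the fit, thresholds, the replicate number as a block and leaving out each array; 5 more were added after the data were seen. A planned comparison of RNA quality from control probe sets could not be run, because the table holds no rows named as control probe sets. Figures were drawn with matplotlib.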

Results

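Gene expression was measured on 17 arrays of whole mouse retina: 6 from control mice, 6 from mice with 12 weeks of streptozotocin diabetes and 5 from mice whose diabetes was treated after 6 weeks with islet transplantation and insulin pellets for 6 more weeks. The series asks about hyperglycaemic memory, that is, whether changes made by high blood glucose outlast its correction. Arrays of the same group correlated at r = 0.996 to 0.998 across genes, and no array was a copy of another. The main axis of variation, with 33.6% of the variance, set the transplanted arrays (scores of -17.6 to -7.56) apart from the control and diabetic arrays (scores of -0.65 to 10.4). The second axis, with 9.34% of the variance, set control replicates 4 and 5 apart from all other arrays. Levels of lens and pigment epithelium marker genes differed between arrays within groups. Whether high crystallin levels came from carried-over lens was not tested. The average of other lens genes was 5.54 in diabetic replicate 2 but 5.42 in diabetic replicate 6, as in control replicate 4. The lens crystallin Cryaa measured 10.5 in control replicate 3, 10.6, 9.04 and 8.70 in diabetic replicates 2, 3 and 6, and its group mean was 7.16 ± 1.67 (SD, n = 6) in control, 8.08 ± 1.74 (n = 6) in diabetic and 7.13 ± 0.67 (n = 5) in transplanted retinas. The labels give no day or batch of processing, so a batch that coincides with a group cannot be told apart from it.

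**Figure D1:**
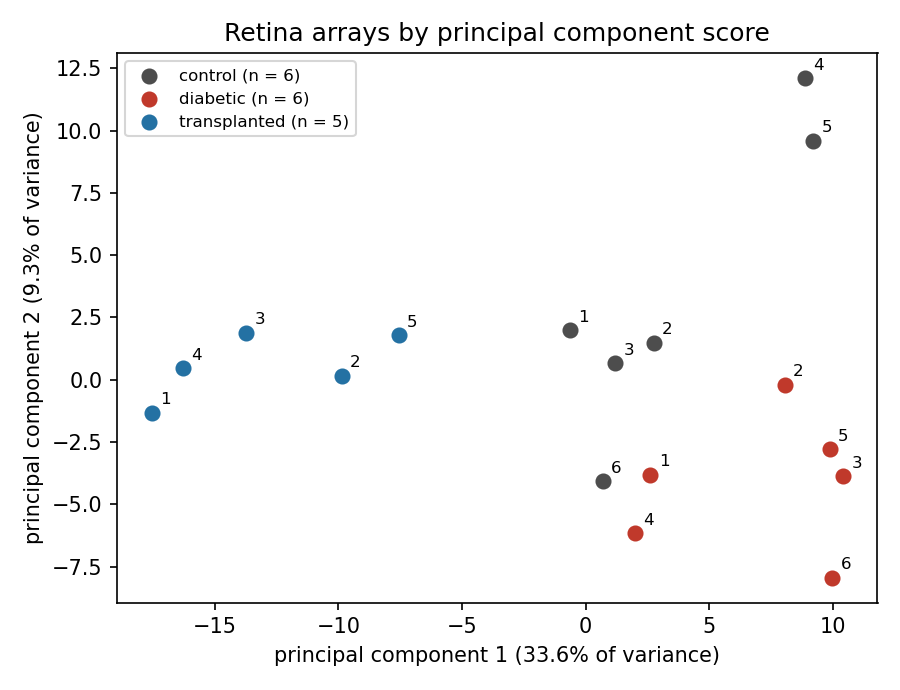
Scores of the 17 retina arrays on the first and second principal components of the log2 expression values (33.6% and 9.34% of the variance), coloured by group and numbered by replicate. All 5 transplanted arrays lie at -7.56 or lower on the horizontal axis, and control replicates 4 and 5 lie highest on the vertical axis.

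The comparison of diabetic with control retinas asks what 12 weeks of streptozotocin diabetes changed. Effects of the toxin and of high blood glucose cannot be told apart in it, and no glucose values were used here. Differences were small: 10 genes were higher, 4 were lower, and the largest change was 1.35-fold. The photoreceptor gene Samd7, a Polycomb-associated regulator in rods, rose from 10.67 ± 0.16 to 11.10 ± 0.08 (mean log2 value ± SD, n = 6 each). Oxct1, the enzyme that lets tissues burn ketone bodies, rose by 0.32 on the log2 scale, Fscn2, an actin-bundling protein of photoreceptors, by 0.29, and Stat3, a transcription factor of cytokine and stress signalling, by 0.27. Rnf123, a ubiquitin ligase, fell by 0.32, and the uncharacterised gene AI413582 fell by 0.29.

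Further rises were found in Usp48 (0.20), Ndrg1 (0.18), Zranb1 (0.17), Mpp6 (0.17), Uri1 (0.16) and the splicing factor Srsf2 (0.16), and further falls in Abhd17b (-0.22), which removes palmitate from synaptic proteins, and Ubxn2a (-0.19), all as log2 changes. Adjusted p-values of these 14 genes in limma ran from 0.0341 for Oxct1, Samd7 and Stat3 to 0.0457 for Zranb1. All 6 diabetic arrays lay on the same side of the control mean for each of them. The genes were called from these same arrays, so this is no separate support. At an unadjusted p below 0.05, 2512 of 24011 genes (10.5%) differed, where 5% would by chance. None of the 14 called genes reached a 1.5-fold change.

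Lists of inner retinal neuron markers were shifted down in diabetic retinas at the preset correlation, although camera called none of them without control replicates 4 and 5. The list of 17 measured ganglion cell genes shifted down (median log2 change of -0.13, camera adjusted p = 6.95e-05; adjusted p = 0.72 with an estimated correlation). Among its members, the synuclein Sncg differed by -0.26, the microtubule regulator Stmn2 by -0.19 (-0.10 without control replicates 4 and 5) and the surface protein Thy1 by -0.18 (-0.10 without control replicate 2); 0 were called over all genes and 1, Sncg, when adjusted over the list alone. The 16 bipolar cell genes shifted down by a median of -0.07 (camera adjusted p = 0.00195, adjusted p = 0.72 with an estimated correlation), with 0 called over all genes and 3 adjusted over the list alone, namely Car8 (-0.19), the Purkinje and bipolar cell protein Pcp2 (-0.32) and the rod bipolar kinase Prkca (-0.12). Without diabetic replicate 1 the bipolar median was -0.04 (camera adjusted p = 0.0256). The 17 amacrine cell genes had a median of -0.06 (camera adjusted p = 0.0463; adjusted p = 0.72 with an estimated correlation), with 2 lower when adjusted over the list alone, among them Calb2 (-0.26). This shift was called in 10 of 17 fits that left out a single array (camera adjusted p of up to 0.221) and not without the dimmest 40% of genes (0.0728). Control replicates 4 and 5 had the highest ganglion cell averages of the 12 arrays, and without both the ganglion median was -0.08 and the bipolar median -0.06 (camera adjusted p = 0.128 for each), and the amacrine median -0.02 (adjusted p = 0.312). With the crystallin and pigment epithelium levels as covariates, the ganglion list (median -0.07, camera adjusted p = 0.136) and the amacrine list (-0.04, adjusted p = 0.181) were not shifted, whereas the bipolar list was (-0.08, adjusted p = 0.0244). Rod and cone photoreceptor lists were not shifted, with medians of 0.01 and -0.03. The crystallin list, used as a marker of lens without a test of that origin, had a median of 0.06 in the same comparison. The pigment epithelium list had a median of -0.05, and neither list was shifted in camera (adjusted p = 0.0724 and 0.215).

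Genes of the circadian clock were higher in diabetic retinas as a group. The 19 measured members had a median change of 0.07 (camera adjusted p = 6.95e-05; adjusted p = 0.128 with an estimated correlation), and this was the only list called by fry (adjusted p = 0.0154). No member was called over all genes, and 7 were higher when adjusted over the list alone. The negative regulators Cry2 and Per2 differed by 0.25 and 0.24, and Arntl, which drives them, by 0.14. Of 26 genes of gliosis and retinal stress, Stat3 alone was called over all genes, and Mt2, a metallothionein, joined it when adjusted over the list alone (0.42, adjusted p = 0.205 over all genes). The glial filament Gfap, whose rise marks activated Mueller cells, differed by -0.07 (adjusted p = 0.521), at 5.77 ± 0.07 in control retinas, near the array median of 5.73. Vegfa differed by 0.08 (adjusted p = 0.59), the thioredoxin inhibitor Txnip, which responds to glucose, by 0.23 (adjusted p = 0.241), and the histone methyltransferase Setd7 by -0.18 (adjusted p = 0.737), which was 0.00 without control replicate 5.

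The 14 calls depended on single arrays. The count was 0 without control replicate 4, diabetic replicate 2 or diabetic replicate 6, 2 without control replicate 5, 4 without control replicate 1, 6 without control replicate 2, 7 without diabetic replicate 5, 8 without transplanted replicate 2, 9 without diabetic replicate 1 or 3 and 71 without control replicate 6; it was also 0 when only these 2 groups were fitted, without control replicates 4 and 5 together, without the 4 arrays of high Cryaa and with the crystallin and pigment epithelium levels as covariates.

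**Figure D2:**
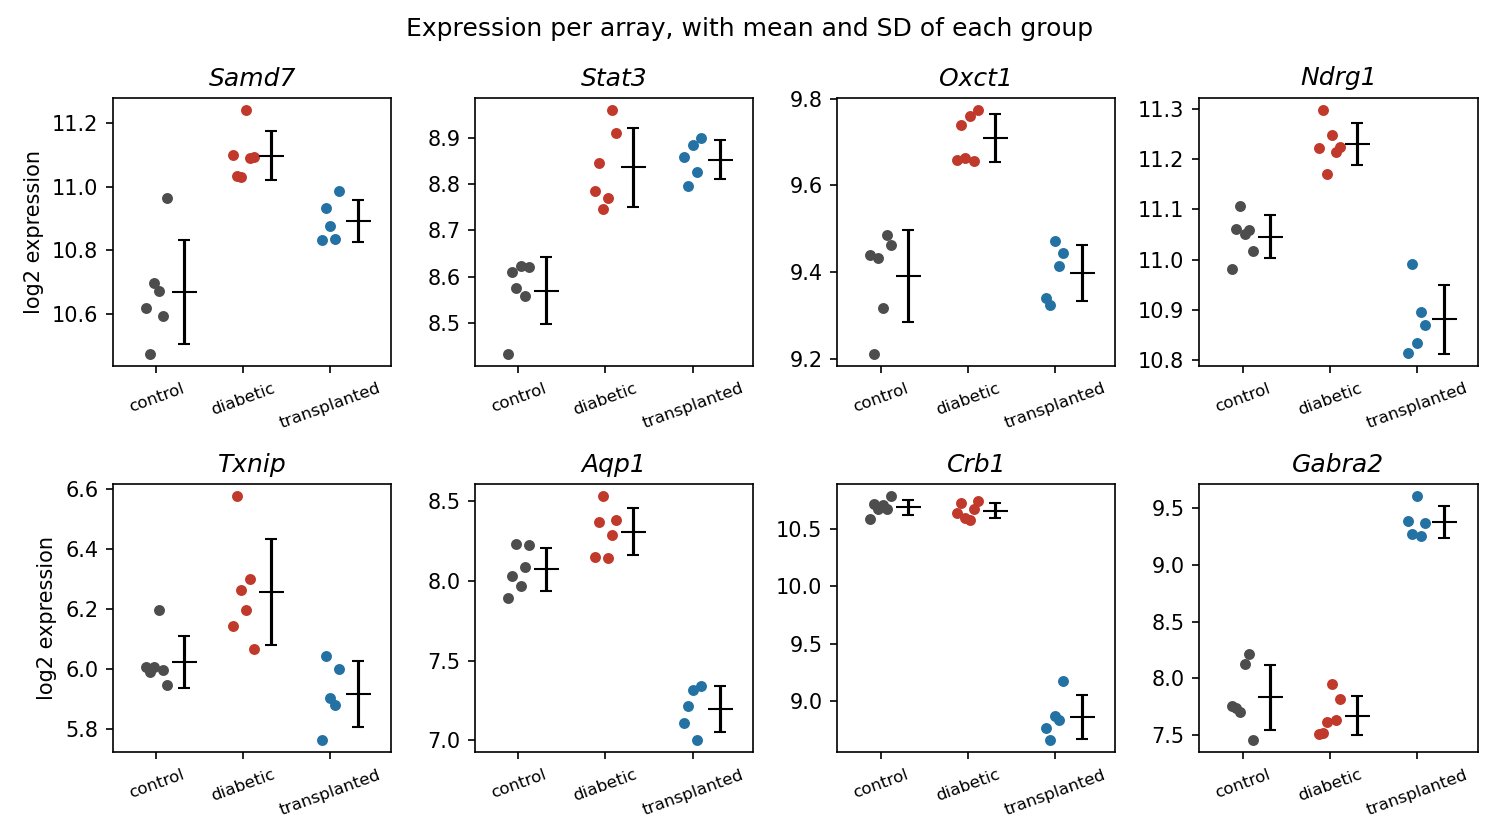
Expression of 8 genes on each array (points, log2 scale; vertical axes differ and do not start at 0), with the mean and SD of each group beside the points (control n = 6, diabetic n = 6, transplanted n = 5). Stat3 was raised in diabetic and transplanted retinas, Oxct1 in diabetic retinas, and Crb1 and Gabra2 of all transplanted arrays lay outside the range of the other groups.

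The comparison of transplanted with control retinas asks what differed from health after 6 weeks of diabetes and 6 weeks with islets. It gave many more genes, 1106 higher and 1031 lower, with a median change of 1.16-fold among them. The GABA receptor subunit Gabra2 rose 2.92-fold, from 7.83 ± 0.28 (n = 6) to 9.38 ± 0.14 (n = 5). Crb1, an apical polarity protein at the outer limiting membrane, fell by 1.84 on the log2 scale, from 10.69 ± 0.07 to 8.86 ± 0.19 (3.57-fold, limma adjusted p = 2.01e-10). The largest falls were in small nucleolar and Cajal body RNAs, which guide the modification of ribosomal and spliceosomal RNA, led by Snord13 with a change of -2.56 (adjusted p = 1.16e-08).

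Among the further rises were the fibronectin-domain gene Fndc1 (log2 change of 1.14), the small GTPase Rras (0.84), the complement inhibitor Cd59a (0.83), the metallothionein Mt2 (0.65), the collagen chain Col6a1 (0.64) and the splicing regulator Hnrnph2 (0.60). The rises of Olfr310, Ighv2-2 and Mir194-2 (0.63, 0.61 and 0.63) are uncertain, because members of such families share sequence that probes may not tell apart. With the score of variation within groups as a covariate they were 0.29, 0.43 and 0.33. Among the further falls were Scarna2 (-2.09), Snord14e (-1.72), Scarna13 (-1.70), Snora73b (-1.44), Snord15a (-1.23), the elongation factor gene Supt4a (-1.12), Snord66 (-1.06) and Snora31 (-1.02); Scarna2 varied widely among transplanted arrays (SD 1.27). Of 105 small nucleolar RNAs, a group chosen after the values were seen and given no set test, 49 were called lower and 2 higher, with a median of -0.19, whereas 19638 protein-coding genes had a median of 0.00. Of all called genes, 47 changed at least 1.5-fold, 13 upwards and 34 downwards.

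Of the lists, only oxidative phosphorylation was shifted (36 genes, median -0.04, camera adjusted p = 0.0197; adjusted p = 0.618 with an estimated correlation). It was not shifted without control replicate 2 (camera adjusted p = 0.0546) or 3 (0.0514), without the 4 arrays of high Cryaa (0.0564) or without the dimmest 40% of genes (0.0669). Over all genes 8 of its members fell and 1 rose, against 14 and 1 adjusted over the list alone. The complex I subunits Ndufs1 (-0.12) and Ndufb5 (-0.30), the succinate dehydrogenase subunit Sdha (-0.09) and the ATP synthase subunit Atp5a1 (-0.11) were among those that fell. In the list of the unfolded protein response, which was not shifted (camera adjusted p = 0.0688), 5 members fell over all genes and 6 adjusted over the list alone. They included the asparagine synthetase Asns (-0.61), the stress transcription factor Ddit3 (-0.23), the disulfide isomerase Pdia4 (-0.29) and the glutathione-degrading Chac1 (-0.17). Of the gliosis and stress list, Stat3 (0.28, adjusted p = 0.000654), Mt2, Mt1 (0.30) and the endothelin Edn2 (0.15) rose, 4 over all genes and 5 adjusted over the list alone, with no fall. Gfap differed by -0.08 (adjusted p = 0.234).

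Of the called cone, amacrine and synaptic genes more rose than fell, whereas 1 ganglion cell gene was called lower. The cone transducin Gnat2 rose by 0.32 and the potassium channel subunit Kcne2 by 0.19, and 3 of the 14 cone genes rose over all genes, against 6 that rose and 1 that fell adjusted over the list alone. The neuropeptide Sst (0.44), the secreted synaptic organiser C1ql2 (0.42) and the reelin adaptor Dab1 (0.33) rose among the amacrine genes, of which 5 rose and 1 fell over all genes, and 8 rose and 2 fell adjusted over the list alone. Among synaptic genes, the AMPA receptor subunits Gria1 (0.32) and Gria2 (0.18) rose. The glial water channel Aqp4 rose by 0.24 (adjusted p = 0.00271). Values that did not pass the test included Glul (0.00), the glial potassium channel Kcnj10 (-0.23), the cone opsins Opn1sw (0.08) and Opn1mw (0.01), the ganglion cell markers Rbpms (-0.09) and Pou4f1 (-0.26, and -0.32 to -0.16 in other settings), the microglial Aif1 (0.02), Vegfa (0.07), Angpt2 (0.02), the pericyte receptor Pdgfrb (-0.17), Txnip (-0.11), Setd7 (-0.30, and -0.13 without control replicate 5), Cryab (0.00) and Cryaa (-0.03, and 0.63 without control replicate 3).

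The count of 2137 fell to 1274 without transplanted replicate 1 and 1307 without transplanted replicate 4, to 923 without control replicates 4 and 5, and to 577 when the score of each array on the main axis of variation within groups was a covariate, of which 520 were among the original calls. In that fit the 2137 genes kept a median of 80.9% of their change, and 38.9% of the variance of the score lay between groups. Of the genes named above, Scarna2, Sdha, Ndufb5, Atp5a1, C1ql2, Dab1, Ddit3, Gria2, Edn2, Kcne2, Chac1 and Olfr310 were not called in it; the change of Dab1 was 0.20 and that of Snord15a -0.80 there, and Olfr310 was not called in 9 of 32 other settings.

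The comparison of transplanted with diabetic retinas asks what the treatment changed at equal time after streptozotocin. A batch or a genetic background that coincides with the transplanted group would enter this comparison and the one with control alike. It gave the most genes, 2146 higher and 1947 lower, with 53 and 38 of them changed at least 1.5-fold. Crb1 (-1.80) and Snord13 (-2.09) were again lower and Gabra2 (1.71) and Fndc1 (1.34) higher. Aqp1, a water channel, fell by 1.12 on the log2 scale, from 8.31 ± 0.15 (n = 6) to 7.19 ± 0.14 (n = 5), and its change against control was -0.88 (adjusted p = 1.71e-05). The glucose-responsive Txnip fell by 0.34 (limma adjusted p = 0.00593) and the main retinal glucose transporter Slc2a1 by 0.22 (adjusted p = 0.00647).

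Of the 40 lists, 4 were shifted between transplanted and diabetic retinas: amacrine, bipolar and cone markers were higher, and the unfolded protein response was lower. Of 17 amacrine genes, 9 rose and 1 fell over all genes as well as adjusted over the list alone (median 0.14, camera adjusted p = 0.0032, adjusted p = 0.508 with an estimated correlation), with Sst at 0.51, C1ql2 at 0.47 and Dab1 at 0.39 (at the least 0.25 in other settings). Of 16 bipolar cell genes, 5 rose, against 7 that rose and 2 that fell adjusted over the list alone (median 0.12, camera adjusted p = 0.014; adjusted p = 0.579 with an estimated correlation), among them Pcp2 (0.69), the G protein subunit Gng13 (0.53) and Car8 (0.22). The bipolar list was not shifted without transplanted replicate 3 (median 0.09, camera adjusted p = 0.0571). Of 14 cone genes, 4 rose, against 5 adjusted over the list alone (median 0.11, camera adjusted p = 0.0219; adjusted p = 0.508 with an estimated correlation): Gnat2 (0.40), Gnb3 (0.18), the phosphodiesterase subunit Pde6h (0.35) and Kcne2 (0.24). The cone list was not shifted without the 4 arrays of high Cryaa (camera adjusted p = 0.104), without the dimmest 40% of genes (0.0598) or with the covariate for variation within groups (0.0712). With that covariate Pde6h changed by 0.19 (adjusted p = 0.162) and Gnb3 by 0.17 (adjusted p = 0.0644), and Pde6h was not called without the arrays of high Cryaa either. The ganglion cell list (median 0.06, camera adjusted p = 0.412) and the horizontal cell list (-0.07, adjusted p = 0.714) were not shifted, although Sncg rose by 0.37.

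Genes of protein folding stress were lower. In the list of the unfolded protein response, 10 members fell and 1 rose, over all genes and adjusted over the list alone (22 genes, median -0.12, camera adjusted p = 0.011; adjusted p = 0.579 with an estimated correlation). Herpud1, which serves the degradation of misfolded proteins, fell by 0.45, Asns by 0.41, Ddit3 by 0.30 and Chac1 by 0.26. The list was not shifted without diabetic replicate 4 (median -0.09, camera adjusted p = 0.0945). The cytosolic chaperones Hsp90aa1 (-0.45) and Hspa1b (-0.60) and the mitochondrial Hspd1 (-0.58) fell as well, although the heat shock list was not shifted in camera (adjusted p = 0.202). Among glycolysis genes, 6 rose and 3 fell over all genes, against 7 and 3 adjusted over the list alone; Aldoa (0.37), Pfkp (0.22), Tpi1 (0.29) and the pyruvate dehydrogenase kinase Pdk2 (0.33) rose, and Slc2a1 was among those that fell. The glycolysis list was not shifted (camera adjusted p = 0.211). The insulin receptor gene Insr fell by 0.23, and the hypoxia-responsive Ndrg1 by 0.35 (adjusted p = 6.54e-06). Of the clock genes, 6 fell and 2 rose over all genes, against 6 and 4 adjusted over the list alone, with Cry1 (-0.43), Cry2 (-0.39) and Per2 (-0.28) among those that fell and Dbp (0.30) among those that rose. The clock list was not shifted (median -0.01, camera adjusted p = 0.563).

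The rises of Olfr310 (1.04), Ighv1-75 (0.97), Esp18 (0.96), Mir297a-4 (0.89), Klra13-ps (0.84) and Ifna4 (0.80) belong to families of near-identical genes and are uncertain. Their smallest changes in other settings were 0.67, 0.54, 0.47, 0.74, 0.52 and 0.40, respectively. Bhmt, a methyltransferase of betaine and homocysteine, rose by 0.87, but was not called with the covariate for variation within groups (0.26, adjusted p = 0.166) or without the 4 arrays of high Cryaa. Scarna2 (-1.90), Scarna13 (-1.65), Snora73b (-1.18), Snord15a (-1.13), Supt4a (-1.06), Snord14e (-1.05) and Snord66 (-0.94) fell. With the covariate for variation within groups Snord15a changed by -0.66 and Snord14e by -0.61. The count of 4093 fell to 1271 without the 4 arrays of high Cryaa, 3 of them diabetic, and to 1381 with the covariate for variation within groups, of which 1248 were among the original calls and in which the 4093 genes kept a median of 80% of their change. Scarna2, Hspd1 and Slc2a1 were not called in either fit, Txnip was not called with the covariate, and Snord14e, Cry1, Ighv1-75, Esp18 and Ifna4 were not called without the 4 arrays.

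**Figure D3:**
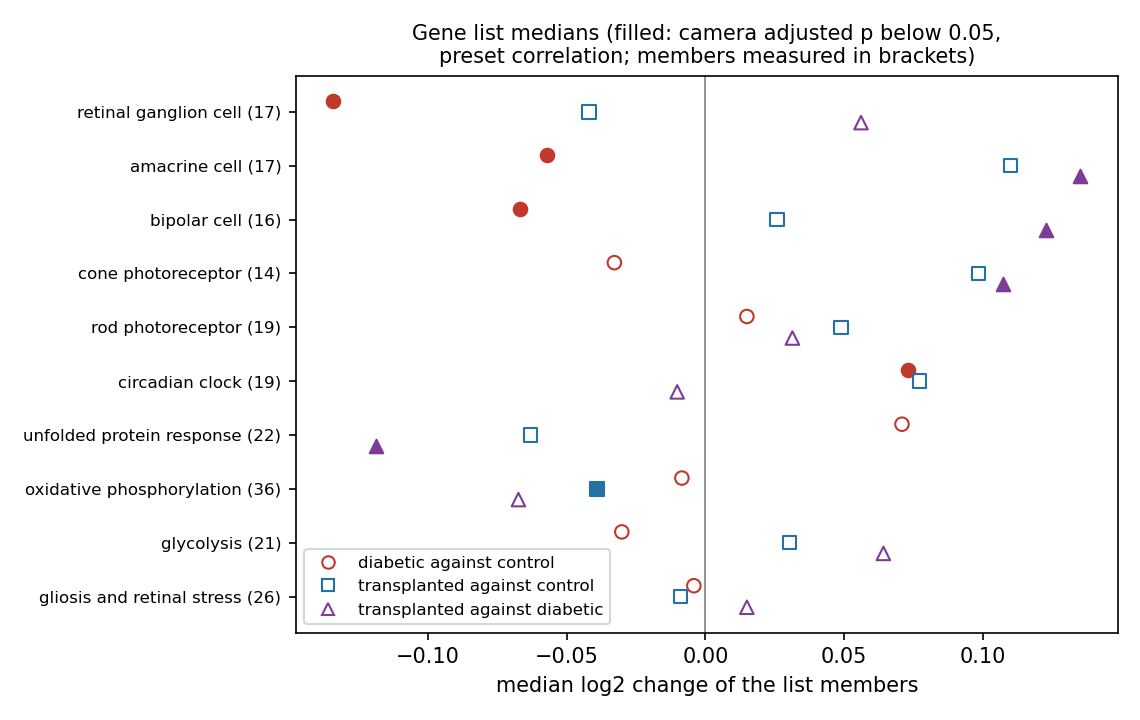
Median log2 change of the measured members of 10 gene lists (numbers of members in brackets) in the 3 comparisons; filled symbols mark a camera adjusted p below 0.05 at the preset correlation, which no list kept with an estimated correlation. The ganglion cell median was -0.13 in diabetic against control retinas, and the amacrine median was 0.14 in transplanted against diabetic retinas.

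Whether diabetic changes were also present after transplantation was asked of single genes and of all genes together. Stat3, AI413582, Uri1, Rnf123 and Samd7, 5 of the 14 genes changed in diabetic retinas, were also called the same way in transplanted against control retinas. Stat3 was 0.27 above control in diabetic and 0.28 above control in transplanted retinas on the log2 scale, and the difference between both was 0.02 (adjusted p = 0.832). Oxct1, in contrast, was 0.01 from control in transplanted retinas (adjusted p = 0.953) and differed from diabetic ones by -0.31 (adjusted p = 0.000445). In all, 10 of the 14 genes were called in the opposite direction in transplanted against diabetic retinas: Oxct1, Fscn2, Mpp6, Usp48, Zranb1, Srsf2, Abhd17b, Ubxn2a, Samd7 and Ndrg1. Samd7 lay between the other groups, at 10.89 ± 0.07 (n = 5), and Ndrg1 was below control after transplantation (-0.16, adjusted p = 0.00382). A batch or a genetic background that coincides with the transplanted group would enter all these values. A change kept or returned cannot be told apart from it.

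Independent lists of these sizes would share 0.632 genes in the same direction for the first count and 1.17 genes in the opposite direction for the second; arrays shared by the contrasts can add to such counts. Both counts were 0 under each setting that removed the diabetic calls, such as leaving out control replicate 4. Across all genes, the change of diabetic retinas correlated with that of transplanted retinas against the same controls at r = 0.02, below the value of 0.479 that unchanged groups give through shared controls, and at r = -0.12 (SD 0.10 over 20 splits) when the control arrays were split between the comparisons (-0.19 to -0.05 without single arrays, and 0.0134 without the 4 arrays of high Cryaa). The covariance of 0.000149 differed from the simulated covariance of 0.00132 by -0.00117. The change of diabetic retinas correlated with the difference between transplanted and diabetic retinas at r = -0.493, against -0.475 for unchanged groups, and at r = -0.283 (SD 0.0752) with the diabetic arrays split, which became -0.0405 without the 4 arrays of high Cryaa; the covariance differed from the simulated one by -0.00307. These correlations are across genes, which are not independent replicates.

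Over the 3 groups, the moderated F called 3327 of 24011 genes. Among genes called in several contrasts, the smallest F p-values belonged to Crb1, Snord13, the G protein subunit Gng3, Gabra2, Snord104, Aqp1, Get3, Scarna13, the galactosyltransferase B4galt1 and Mir674. Gng3 was 0.54 and B4galt1 0.59 above control in transplanted retinas, and Get3, which inserts tail-anchored proteins into membranes, was below control (-0.47). Mir674 was lower in transplanted than in diabetic retinas (-0.75). Transplanted retinas differed in the same direction from control and from diabetic retinas for 1655 genes and in opposite directions for 1 gene, Samd7. The same transplanted arrays entered both contrasts; independent lists of these sizes would share 182 genes in the same direction. With the transplanted arrays split between the contrasts, a mean of 386 genes were called in both in the same direction and 0.15 in opposite directions over 20 fits, in which a mean of 813 and 1902 genes were called. Independent lists of those sizes would share a mean of 49.6 genes, both directions together.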

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

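The tests of variation within groups on the transplanted arrays and on Crb1 and Gabra2, and those of inner retinal list means and of ganglion against rod and cone genes, were chosen after the results were seen. For the other tests of explanations in this part, predictions were written beforehand. Those tests were not part of the design fixed before the data were examined, and some predictions name patterns of these data, such as lower Crb1. A single array stood apart from the rest of its group in 25 of 324 combinations of a named gene and a group (7.72%), by a gap to the nearest array that was large against the range of the group; chance gives about 1 in 20.

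Cryaa in control replicate 3 had the widest gap, with a log2 value of 10.5 against 6.88 for the next array. The histone methyltransferase gene Setd7 measured 8.42 in control replicate 5, with 7.51 next. In other control arrays, Aif1 (5.34), Gria1 (7.77), Pou4f1 (6.66) and Txnip (6.20) stood apart in replicate 4, Arntl (10.5) in replicate 5, Aqp4 (9.55), Dbp (10.4) and Vegfa (9.64) in replicate 6, Stat3 (8.43) and Mir297a-4 (8.09) in replicate 1 and Thy1 (8.63) in replicate 2. In diabetic arrays, Col6a1 (8.02) and Pcp2 (9.65) stood apart in replicate 1, Fndc1 (7.52) and Gfap (5.83) in replicate 5, Samd7 (11.2) in replicate 4 and Snord13 (11.1) in replicate 6. In transplanted arrays, Mpp6 (9.13), Mt1 (10.4) and Pou4f1 (6.28) stood apart in replicate 3, Pdgfrb (6.08) and Srsf2 (11.2) in replicate 4 and Aqp4 (9.76) in replicate 2.

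The separation of transplanted retinas from both other groups was larger than chance splits of the arrays give. Of 100 splits for each contrast, the real one included, 1 gave as many genes for transplanted against control (2137, with 96 as the highest other) and 1 for transplanted against diabetic (4093, with 1020 as the highest other); the real split of the 3 groups was also the only 1 of 100 with 3327 genes in the F test (highest other 8). For transplanted against control, tissue carried over from outside the neural retina is argued against as the whole cause. The largest median there among lists of pigment epithelium, lens, muscle, cornea, blood and optic nerve was that of pigment epithelium at -0.118. For transplanted against diabetic no such prediction was tested, so carried-over tissue stays open there. In that contrast the crystallin median was -0.08. The count fell to 1271 without the arrays of high Cryaa, but was 3987 with crystallin and pigment epithelium levels as covariates. A gradient between arrays that also runs within groups may contribute: its gene pattern among diabetic arrays alone correlated with the transplanted change at r = 0.313 across genes, but at 0.0625 to 0.306 when single diabetic arrays were left out, so it cannot be told apart from the group difference. A batch of processing that coincides with the group stays open, as do the treatment itself and a substrain difference, which is raised below for Crb1 and Gabra2.

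The change of Crb1 and Gabra2 stood far outside the usual size, and it did not follow the gradient, as with that covariate the smaller share of the change kept by either gene was 97.1%. As a hypothesis, mice of another C57BL/6 substrain in the transplanted group could differ in both genes, since both are known to carry differences between the J and N substrains; the labels give 1 strain for all groups. Nnt, part of which is deleted in the J substrain, was higher in transplanted than in control retinas by 0.338 on the log2 scale (limma adjusted p = 0.0125) and than in diabetic retinas by 0.403 (adjusted p = 0.00229). All 5 transplanted arrays lay above every diabetic array (lowest 7.03, highest diabetic 6.98), and 4 lay above all controls, of which 1 measured 7.07 and the next 6.80. Nnt thus moved in the direction predicted for the substrain, and Crb1 and Gabra2 of all transplanted arrays lay outside the range of the other groups. The size of the Nnt change against control lies between the bounds set beforehand (over 0.5 in every array for the substrain, under 0.2 against it). By that rule a substrain difference and an effect of treatment cannot be told apart. The rule uses the size of the Nnt change alone. Only part of Nnt is deleted, so a single value per gene can understate the change, and a value below 0.5 does not weigh against the substrain. The rule also leaves out Crb1, which was lower in transplanted than in control retinas (-1.84), and Gabra2, which was higher (1.55). The hypothesis was raised from these genes, so they do not test it separately.

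The 14 genes called between diabetic and control retinas were reached by 1 of 100 splits, the real one (highest other 3), which does not bear on the lists.

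The lower inner retinal lists in diabetic retinas were not beyond the spread of array means, with exact permutation adjusted p-values of 0.0881 for ganglion, 0.0699 for bipolar and 0.0974 for amacrine genes. With the covariate for the main gradient within groups the ganglion cell median kept 104% of its size. That score differed little between diabetic and control arrays (3.17 ± 5.08 against 2.33 ± 7.49, exact permutation p = 0.794), so the covariate could remove little. The fit argues against this axis alone. Other variation within groups stays open, since without control replicates 4 and 5 the ganglion list was not called (median -0.08, camera adjusted p = 0.128). Dilution by lens or pigment epithelium stays open: with both levels as covariates the ganglion cell median kept 54.6% of its size, between the bounds set, the bipolar median 117% and the amacrine median 75.8%. Against it, rods, which dilution would lower too, differed by 0.00 and pigment epithelium was lower in diabetic arrays (7.11 against 7.26), but the ganglion change differed from that of rods by -0.124 (exact permutation p = 0.0996) and from that of cones by -0.098 (exact permutation p = 0.19), within the spread. Fewer or less active inner neurons in diabetes, the biological alternative, were not tested.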

How the results depend on the processing

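The added settings (gradient covariate, crystallin and pigment epithelium covariates, arrays left out together, protein-coding genes only) were chosen after the data were seen. Of 5508 values of named genes under other settings, 0 reversed a call, 289 lost it and 12 gained one; a sign change without a call on either side was counted as no change. The quantile and median settings moved nothing, because all arrays already share 1 distribution, and the other rules for genes on several rows touch 4 symbols; RNA quality was not run, and a pseudocount did not apply. Signal near the floor of 5.07 limits dim genes such as Aif1. Causes were not tested, except that thresholds, fewer arrays and fewer genes act by construction.

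For diabetic against control, the 14 genes became 25 without the dimmest 40% of genes, 31 among protein-coding genes, 7 with array weights, 79 at an adjusted p of 0.1, 37 with the gradient covariate, and 0 in the 2-group fit, at 1.5-fold, with crystallin and pigment epithelium covariates, without control replicates 4 and 5, and without the 4 arrays of high Cryaa; leaving out single arrays gave 0 to 71. The 5 genes called the same way in transplanted against control became 3 with array weights and 0, as did the 10 called the opposite way in transplanted against diabetic, in the 2-group fit, with tissue covariates and without those sets of arrays; single arrays gave 0 to 19. The 10 became 18 without dim genes, 4 with array weights, 22 with the gradient covariate and 25 among protein-coding genes; single arrays gave 0 to 52.

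For transplanted against control, the 2137 genes became 3459 at an adjusted p of 0.1, 47 at 1.5-fold, 577 with the gradient covariate (a median of 80.9% of the change kept) and 923 without control replicates 4 and 5; single arrays gave 1274 to 2181. For transplanted against diabetic, the 4093 became 91 at 1.5-fold, 1381 with the gradient covariate and 1271 without the high-Cryaa arrays; single arrays gave 2872 to 4211. The 3327 genes of the F test became 108 at 1.5-fold, 1066 with the gradient covariate and 1513 without the high-Cryaa arrays; single arrays gave 2191 to 3485.

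Shifted lists numbered 0 in all contrasts with an estimated correlation, and 1, 7 and 11 with fry. For diabetic against control (4) there was 1 without control replicates 4 and 5, the clock list, and single arrays gave 3 to 8. For transplanted against control (1) there were 0 without dim genes or the high-Cryaa arrays, 8 with the gradient covariate, 3 with tissue covariates and 5 without control replicates 4 and 5; single arrays gave 0 to 4. For transplanted against diabetic (4) there were 9 with the gradient covariate, and single arrays gave 3 to 5. The split correlation of -0.12 became 0.0134 without the high-Cryaa arrays (-0.19 to -0.05 without single arrays), and that of -0.283 became -0.0405 without them, -0.438 with tissue covariates and -0.393 without control replicates 4 and 5 (-0.333 to -0.201).

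Replicate numbers do not pair the arrays: of 16 same-numbered pairs, 4 had a correlation over 0.1 and 3 correlated best with their own number. With the number as a block, the 14 genes became 22, of which 7 were among the 14, and the 10 called the opposite way became 16.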

Other observations

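The test of clock gene phase in transplanted retinas and the tests of list means per array were chosen after the results were seen. For the same clock test in diabetic retinas a prediction was written beforehand, but it was not part of the design fixed before the data were examined.

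Averaged per array, clock genes were higher in diabetic (9.22 ± 0.05, n = 6) than in control retinas (9.13 ± 0.03, n = 6), with an exact two-sided permutation p of 0.00649 and an adjusted p of 0.0278 over 30 such tests. They were also higher in transplanted (9.18 ± 0.02, n = 5) than in control retinas (exact permutation p = 0.0108, adjusted p = 0.0325), and transplanted retinas did not differ from diabetic ones (exact permutation p = 0.132, adjusted p = 0.212). The list tests did not call clock genes in transplanted against control retinas (camera adjusted p = 0.241, or 0.741 with an estimated correlation, and fry adjusted p = 0.0684). Oxidative phosphorylation genes were lower in transplanted (8.26 ± 0.02, n = 5) than in control retinas (8.33 ± 0.04, n = 6; exact permutation p = 0.00866, adjusted p = 0.0289). Unfolded protein response genes were lower in transplanted (8.35 ± 0.02) than in control (8.44 ± 0.05; exact permutation p = 0.00433, adjusted p = 0.0278) and diabetic retinas (8.48 ± 0.09; exact permutation p = 0.00649, adjusted p = 0.0278). Amacrine, bipolar and cone averages were higher in transplanted than in diabetic retinas, each with an exact permutation p of 0.00216, the smallest that 462 splits can give (adjusted p = 0.0216). Against control the amacrine (0.10, exact permutation p = 0.00866, adjusted p = 0.0289) and cone averages (0.09, exact permutation p = 0.00649, adjusted p = 0.0278) were higher too. Camera did not call these 2 lists against control (adjusted p = 0.0688 for each). The bipolar average differed from control by 0.07 (exact permutation p = 0.115, adjusted p = 0.202). The ganglion cell average of diabetic retinas differed from control by -0.12 (exact permutation p = 0.0411, adjusted p = 0.0881). These lists were examined because of their shifts, so the tests are not independent of them.

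Small RNAs of the nucleolus and Cajal body were grouped after the values were seen and given no set test: 40 of 105 small nucleolar RNAs were lower and 6 higher in transplanted than in diabetic retinas, with a median of -0.16, and 8 guide RNAs had a median of -0.40. In diabetic against control retinas, 0 of either class were called in limma, with medians of -0.07 and -0.06.

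A different time of day at collection is a candidate explanation for clock gene differences. The prediction took Per and Dbp genes as 1 arm and Arntl and Clock genes as the other. With time of day as the cause, the arms would move in opposite directions. This assumes that the members of an arm move together. In diabetic retinas both arms were higher than in control, by 0.08 (exact permutation p = 0.0108) and 0.11 (exact permutation p = 0.00866) on the log2 scale. Their difference was -0.027 (exact permutation p = 0.418). The arm means thus did not move in opposite directions as predicted. They cannot exclude a shift of time, because members of an arm need not move together. In transplanted against control retinas the first arm was higher by 0.10 (exact permutation p = 0.00216), although its member Hlf was called lower (-0.18, a call lost in 9 of 32 other settings), and the second differed by -0.04, within the spread (exact permutation p = 0.26). The difference of 0.136 (exact permutation p = 0.00216) came mostly from the mean of the first arm. Against diabetic retinas the difference was 0.163 (exact permutation p = 0.00216). The mean of the second arm differed there by -0.14 (exact permutation p = 0.00649) and that of the first by 0.02 (exact permutation p = 0.524). The first arm did not move together there, as its members Dbp (0.30) and Per2 (-0.28) were called in opposite directions. Whether time of day or the group caused these differences cannot be told apart, and collection times are not in the labels.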
